A study of Homo sapiens with 96 samples.

How the data were processed

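Gene expression was measured by paired-end RNA sequencing in 6 human acute myeloid leukaemia (AML) cell lines, HL60, Kasumi1, MOLM13, MV411, OCIAML3 and THP1. Per the labels' protocols, cells received 0.1% DMSO as vehicle, 1 µM GSK2879552, 100 nM all-trans retinoic acid (ATRA) or both drugs for 2 or 4 days. GSK2879552 inhibits lysine-specific demethylase 1 (LSD1, encoded by KDM1A), and ATRA is a ligand of the retinoic acid receptors. RNA was purified from TRIzol lysates with the RNeasy kit and libraries were made with the TruSeq Stranded Total RNA kit, per the labels' protocols. The labels named the treatments DMSO, 552A, ATRA and Combo. The label 552A was read as the GSK2879552 arm, because it was the one protocol arm left and its digits match the end of the compound name. Each of the 48 combinations of line, treatment and day had 2 replicates, which gave 96 libraries. The labels did not say that replicates came from separate cultures, so p-values within a line measure only the spread between these libraries, which may be technical.

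The deposited table held whole-number counts of reads per gene for 60552 gene rows, not normalised. Per the submitters' processing notes, the tools were Trimmomatic 0.36, STAR 2.4.2a and HTSeq 0.6.0, and the genome build was GRCh38. The annotation release and the strand setting of the counting were not given in the sources used here, so overlapping and antisense genes and near-identical paralogs, such as histone and HLA genes, carry an added uncertainty. Gene rows were matched by Ensembl identifier without its version to GENCODE release 29 (GRCh38), which gave symbols, biotypes and coordinates for 56994 rows. The 3508 unmatched rows held 0.0417% of the counts, 50 further rows for pseudoautosomal copies on the Y chromosome held 0 counts, and 17629 rows were 0 in all libraries. Total counts ran from 12.82 M to 40.95 M per library (median 22.88 M). Mitochondrially encoded genes took 0.307 to 7.588% of a library and the 10 most abundant genes took 3.369 to 12.899%. No pair of replicates agreed within sampling noise, since the smallest chi-square per degree of freedom between replicates was 9.902.

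Counts were tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16, TMM normalisation and filterByExpr, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 with no threshold on the fold. Every adjusted p in the text comes from this test unless another is named. Within each line the 16 libraries entered a single fit with 8 groups, which left 8 residual degrees of freedom. For changes common to the lines, the 2 replicates of each line and treatment were summed, and the 24 sums of a day were fitted with the cell line as a block, so that the 6 lines were the replicates. The same fit gave Combo against each single agent and Combo beyond the sum of the single agents on the log2 scale. Differences between day 4 and day 2 were tested on the 48 sums of both days, and differences between lines by an F test of the line-by-treatment terms on the 48 day 4 libraries. The standard error (SE) of a log2 fold change was its size divided by the square root of its F statistic. CPM are normalised read counts scaled by the TMM-adjusted library size, given as mean ± SD of 2 replicates. For a gene with 0 counts in a group, the fold was bounded with 3 counts over the group and written "at least", a bound that covers counting error only.

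Gene lists were tested with camera in limma 3.58.1 with a preset inter-gene correlation of 0.01, adjusted over the 26 lists of a comparison. The lists were fixed before the data were examined and held 463 entries for 459 genes, all matched. They were retinoic acid response, myeloid surface markers, azurophil granule proteins, specific and gelatinase granule proteins, neutrophil function, NADPH oxidase, monocyte and macrophage, dendritic cell, myeloid transcription factors, stem and progenitor, LSD1 complex, cell cycle, cell cycle inhibitors, MYC and ribosome biogenesis, interferon response, antigen presentation, inflammatory cytokines and receptors, death receptor and pro-apoptotic, anti-apoptotic, megakaryocyte and erythroid, mast cell, basophil and eosinophil, lymphoid, integrated stress response, heat shock and unfolded protein response, mitochondrially encoded genes as a sign of RNA quality, and replication-dependent histones as a sign of RNA selection. The genes named were chosen by a rule also fixed before the data were examined, and some that met it are not reported here. It took, for each day 4 comparison across lines, the 6 largest rises and 6 largest falls among called genes with a mean log2 CPM of at least 1 and the same direction in all 6 lines. It also took up to 4 members of each list with the smallest p, the 2 largest rises and falls per line and single agent among called genes whose replicates were separated, and KDM1A, RARA, CYP26A1, ITGAM, CD86, CD38, GFI1B and MYC. Small nuclear and nucleolar, signal recognition particle, ribosomal protein, mitochondrial and clone-named genes were passed over in the choice by size of change. Genes named because they were called in all 6 lines or differed between days were chosen after their values were seen.

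The procedures were tested on simulated data, drawn from the measured means and library sizes with 200 genes changed. Within a line (18267 genes) edgeR recovered 10% and 22% of genes changed by 1 and -1 on the log2 scale and 82% and 88% of those changed by 2 and -2, with 6 false calls. Across 6 lines (22759 genes) it recovered 56%, 62%, 98% and 94%, with 10 false calls. For Combo beyond the sum it recovered 34%, 18%, 80% and 88% with 10 false calls, for the day difference (23090 genes) 30%, 26%, 90% and 82% with 8, and for differences between lines (20157 genes) 10%, 6%, 62% and 58% with 4. A further run with MOLM13 (18209 genes) added the measured GC trends and drew the counts with less random spread than the first run. There the uncorrected test recovered 46%, 48%, 96% and 92% with 0 false calls and the corrected test 82%, 94%, 100% and 100% with 14. These values compare the tests with each other only. Because of the smaller spread they cannot be set beside the first run or read as the recovery in the measured libraries.

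Alternatives fixed before the data were examined were the size factors of DESeq2 in edgeR, no filter on low counts, the DESeq2 1.42.0 test, the replicate number as a block, no block on the line, each library or line left out, an estimated inter-gene correlation and a threshold of 0.01 for shared calls. A correction for the smooth trend of each library on gene GC content and length, and a fit without 5 libraries whose GC trend lay more than 3 scaled median absolute deviations from the median of their line, were added after seeing the data. Tables were prepared in Python 3.11.15 and plots were drawn with matplotlib 3.10.9.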

Results

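Gene-level read counts were available for 6 AML cell lines treated with DMSO, the LSD1 inhibitor GSK2879552 (552A), ATRA or both (Combo) for 2 or 4 days. Kasumi1 carries the RUNX1-RUNX1T1 fusion, MOLM13, MV411 and THP1 carry KMT2A fusions, and OCIAML3 carries an NPM1 mutation. Each of the 48 groups had 2 replicates and each of the 96 libraries held 12.82 M to 40.95 M counts (median 22.88 M). The comparisons asked which genes each drug changed, and whether the combination changed differentiation genes beyond the single agents. Replicates of 1 group differed mainly along a trend with gene GC content. The main axis of the replicate differences held 73.9% of their variance over 9842 genes, and its loadings correlated with gene GC content at r = -0.899 across genes, which are not independent replicates. In 5 libraries this trend stood apart from the rest of their line: Kasumi1 Combo day 4 replicate 1, MOLM13 552A day 4 replicate 1, MV411 Combo day 4 replicate 2, OCIAML3 552A day 2 replicate 2 and THP1 552A day 2 replicate 2. Their slopes were -0.69, -0.49, -0.72, -0.996 and -0.85 in log2 per 10% GC against the mean of their line. Those of the other libraries ran from -0.58 to 0.40. At day 4, replicate 2 of MV411 DMSO (-0.58), OCIAML3 Combo (-0.55) and HL60 ATRA (-0.53) was steeper than the MOLM13 library that stood apart. Apart from MV411 day 4 replicate 2 and MOLM13 day 2 replicate 2 (-0.04), all DMSO libraries had positive slopes. The 552A and Combo libraries had both signs in every line, as did ATRA libraries outside MV411. Comparisons with DMSO can therefore carry part of the GC trend, also without the 5 libraries.

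**Figure D1:**
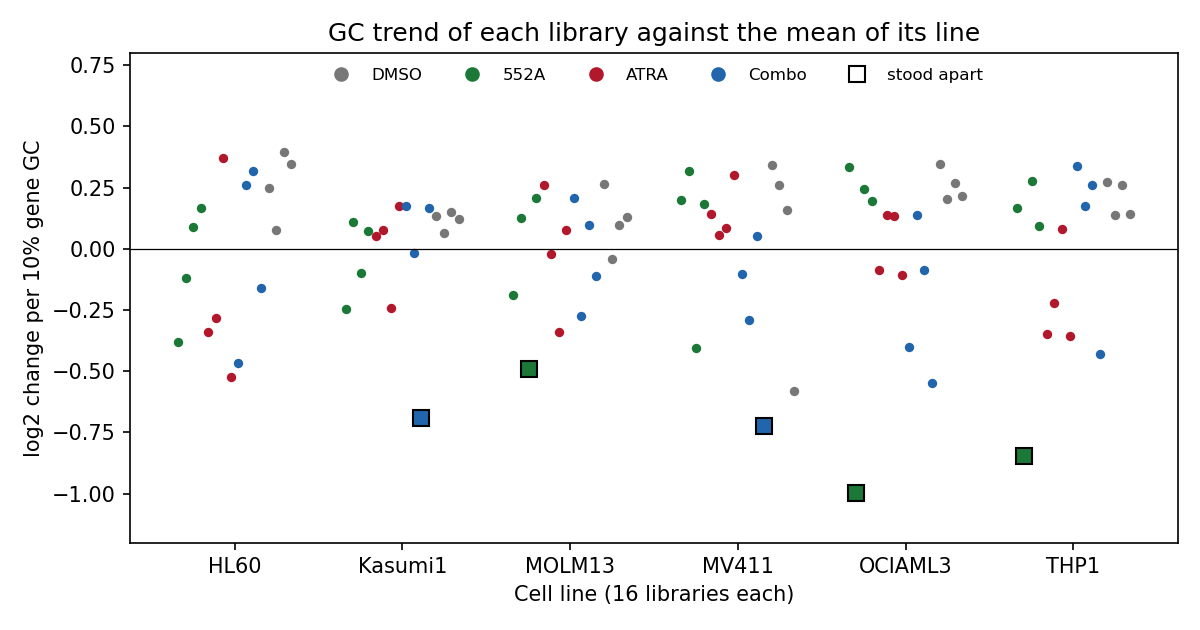
Trend of each library with gene GC content, as the log2 change per 10% GC against the mean of its line (y axis), for the 16 libraries of each cell line (x axis), coloured by treatment. Squares mark the 5 libraries that stood apart, from -0.49 to -0.996.

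The targets of both drugs were expressed in all lines. KDM1A (ENSG00000004487.15, chromosome 1, 23019443 to 23083689, plus strand), which encodes LSD1, had 89.3 to 355 CPM over the day 4 group means. With 552A at day 4 its log2 fold change across lines was -0.06 ± 0.15 (SE, n = 6 lines; adjusted p = 0.981). The compound acts on the protein, so this transcript does not check the treatment labels. CYP26A1 (chromosome 10, 93073475 to 93077890, plus strand), the retinoic acid-degrading enzyme induced by its own substrate, rose 518-fold with ATRA at day 4 across lines (log2 9.02 ± 1.02, adjusted p = 0.000107) and 684-fold with Combo (log2 9.42 ± 1.01, adjusted p = 7.25e-05). It was called in 5 lines with each, but was too low to be tested in Kasumi1, with 0.0641 ± 0.0206 CPM with DMSO, 0.317 ± 0.366 with ATRA and 0.11 ± 0.038 with Combo (SD, n = 2). All 6 lines together held 8 CYP26A1 counts with DMSO and 1 with 552A at day 4. RARA, the retinoic acid receptor alpha gene, was not called across lines with 552A (-0.25, adjusted p = 0.949), ATRA (-0.32, adjusted p = 0.518) or Combo (-0.70, adjusted p = 0.0782), where it was called without MV411 (-0.79).

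At day 4, 552A alone changed 95 genes across the 6 lines. The B-cell Fc receptor-like gene FCRLA rose 173-fold (log2 7.44 ± 1.30 SE, n = 6 lines, adjusted p = 0.0105). The TLR4 co-receptor gene LY96 rose 35.8-fold (5.16 ± 0.90, adjusted p = 0.0102). HLA-DMB, a chaperone of class II peptide loading, rose 36.8-fold (5.20 ± 0.98, adjusted p = 0.0188). The lysozyme gene LYZ rose 10.1-fold (3.34 ± 0.67, adjusted p = 0.0292). The glycosyltransferase gene GCNT2 rose 9.9-fold (3.31 ± 0.63, adjusted p = 0.0203) and the chromatin reader gene SP140 7.68-fold (2.94 ± 0.31, adjusted p = 0.00013). The rule that named these genes required the same direction in all 6 lines, so their shared direction is not a separate result. Within lines, FCRLA and HLA-DMB were not called in HL60 (adjusted p = 0.114 and 0.168), nor GCNT2 in Kasumi1 (0.0623). ITGAM, which encodes the CD11b integrin of myeloid cells (ENSG00000169896.16, chromosome 16, 31259967 to 31332892, plus strand), rose 6.86-fold (2.78 ± 0.60, adjusted p = 0.0476). Its normalised read count went from 2.76 ± 0.0233 to 61.6 ± 15.1 CPM in HL60, from 1.21 ± 0.0407 to 6.93 ± 0.862 in Kasumi1 and from 27.9 ± 5.48 to 239 ± 40.5 in THP1 (SD, n = 2). The scavenger receptor gene CD163 (6.57 ± 0.73, adjusted p = 0.000219), the calgranulin gene S100A12 (6.86 ± 1.09, adjusted p = 0.00911) and the granzyme gene GZMA (6.53 ± 1.00, adjusted p = 0.00372) rose across lines. Each was higher in the 4 lines in which it was tested and called in 3, the exceptions being CD163 in MV411 (adjusted p = 0.0654), S100A12 in HL60 (0.158) and GZMA in THP1 (0.433). CD86, a costimulatory ligand, missed the threshold across lines (3.45 ± 0.80, adjusted p = 0.0747) although it was higher in all 6 lines and called in 5. Its SE drew on all treatments, and so also on the differences between lines with ATRA and Combo. CD38 (0.14, adjusted p = 0.992), GFI1B (4.97 ± 1.48, adjusted p = 0.222) and MYC (-0.42, adjusted p = 0.957) were not called.

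By list, 552A called 1 of 18 myeloid surface markers, 2 of 22 monocyte and macrophage genes and 1 of 22 antigen presentation genes, all higher. Adjusted over the list alone these counts were 4, 4 and 3. The camera test placed these lists above the other genes (medians 0.57, 0.82 and 0.43, adjusted p = 2.44e-05, 0.000247 and 2.44e-05). These calls were lost when the correlation between genes was estimated (adjusted p = 0.387, 0.313 and 0.387 with an estimated correlation). The cell cycle, MYC and ribosome biogenesis and integrated stress response lists lay lower (medians -0.19, -0.19 and -0.58, adjusted p = 0.0027, 0.0027 and 2.44e-05) with 0 members called by edgeR. These calls were lost as well (adjusted p = 0.683, 0.683 and 0.387 with an estimated correlation). Neutrophil function and lymphoid genes each had 1 call, S100A12 and GZMA, and their lists did not pass (adjusted p = 0.121 for both). The inflammatory list had 1 call, LY96. Azurophil granule proteins had a median of -0.82 and did not pass (adjusted p = 0.0821), nor did the dendritic cell list (0.0781), in which 4 members were higher when adjusted over the list alone. In the LSD1 complex list the median (0.01) and mean (0.32) had the opposite sign to the test, which did not pass (adjusted p = 0.914). Over all genes, 95 of 24199 were called, 92 higher and 3 lower, 1805 had an unadjusted p under 0.05, and DESeq2 called 312. The count was 27 without MOLM13. Of the genes named here, SP140 kept its call with each line left out (2.76 to 3.11), while that of ITGAM ended without any line other than HL60.

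Within single lines 552A changed 172 to 1372 genes at day 4, and most called genes were higher. HL60 had 146 higher and 26 lower, Kasumi1 770 and 156, MOLM13 244 and 60, MV411 627 and 329, OCIAML3 367 and 158, and THP1 942 and 430. Corrected for GC content and length, these were 270 and 114 in HL60, 1307 and 737 in Kasumi1, 395 and 251 in MOLM13, 1392 and 1247 in MV411, 695 and 374 in OCIAML3 and 1930 and 1589 in THP1. In HL60 FCRL4 rose from 0 to 2.83 ± 0.909 CPM, at least 46.8-fold. TMCC3 fell there (1.65 to 0.0704 CPM). In Kasumi1 PI16 rose at least 223-fold to 14.7 ± 1.45 CPM and the sodium channel gene SCN3A at least 98.7-fold. In the same line IGLL1 (-2.94 ± 0.56) and S100P (-2.27 ± 0.37) fell. The GTPase gene GIMAP4 rose at least 53-fold in MOLM13 and at least 83.3-fold in MV411, where FCRLA reached 84 ± 1.81 CPM from 0.279 ± 0.218. MOLM13 gained CD1A (at least 17.9-fold) and had lower AGT (-4.30 ± 0.46) and S100P (-3.37 ± 0.49). MV411 had lower CES1 (-4.14 ± 0.54, adjusted p = 0.000799). IFI44L was called lower there (7.23 ± 8.76 to 0.397 ± 0.32 CPM, adjusted p = 0.0377), but its log2 change was -1.44 without DMSO day 4 replicate 2, where the call ended, as it did without 8 other libraries. OCIAML3 gained CD163 (0.515 ± 0.114 to 194 ± 19.1 CPM). The receptor kinase gene ROS1 fell there (-6.62 ± 0.51), with SHISAL1 (-5.32 ± 0.55), and in THP1 (-4.78 ± 0.36). THP1 also gained the lipid antigen gene CD1B (at least 54.4-fold) and FCRLA (0.058 to 21.7 ± 1.6 CPM). The stem cell factor receptor gene KIT fell from 25.1 ± 0.52 to 2.06 ± 0.0934 CPM (adjusted p = 4.12e-06). LYZ in THP1 went from 339 ± 21.7 to 8450 ± 391 CPM.

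With 552A at day 4, 15 of the 28 interferon response genes tested in Kasumi1 were called higher, while in MV411 2 of 30 were called lower. Antigen presentation genes called higher with 552A numbered 10 in MV411, 9 in THP1, 4 in Kasumi1, 3 in MOLM13, 2 in OCIAML3 and 0 in HL60. Of the myeloid surface markers, 3 were called higher in HL60, 6 in Kasumi1, 4 in MOLM13, 5 in MV411, 2 in OCIAML3 and 6 in THP1. The genes called higher in all 6 lines numbered 16, among them SOAT1, SP140, LYZ, NLRC4, RNF130, SCPEP1, GLIPR1, GPR65, LY96, SLC7A7, RNASE6 and ITGAM, and no gene was called lower in all 6.

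**Figure D2:**
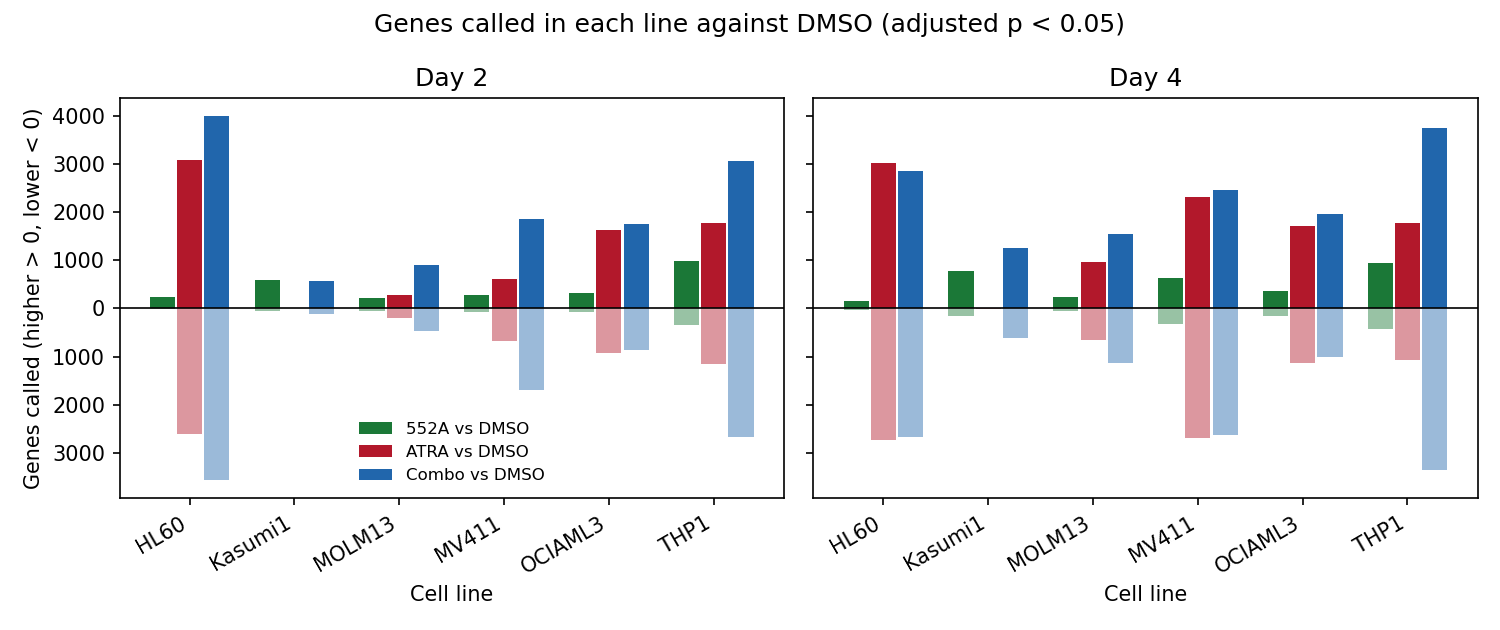
Genes called in each cell line (x axis) against DMSO at day 2 and day 4, with higher genes plotted above 0 and lower genes, in lighter colour, below 0 (y axis, number of genes). With ATRA at day 4, Kasumi1 had 19 called genes and HL60 had 5762.

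ATRA at day 4 raised retinoic acid target genes. TGM2, a transglutaminase, rose 82.5-fold across lines (log2 6.37 ± 0.60, adjusted p = 2.45e-05), and the transcriptional repressor gene HIC1 rose 45.4-fold (5.50 ± 0.70, adjusted p = 0.000461). The retinal reductase gene DHRS3 rose 57.9-fold (5.86 ± 1.10, adjusted p = 0.00587) and the ectoenzyme gene CD38 17.9-fold (4.16 ± 0.68, adjusted p = 0.00287). The sulfotransferase gene CHST15 (5.78 ± 1.03), the synaptotagmin gene SYT2 (5.56 ± 0.75) and the lipid antigen-presenting gene CD1D (5.16 ± 0.86) also rose across lines, with adjusted p from 0.000783 to 0.00502. These 3 were called in 5 lines and not in Kasumi1 (2.52, 0.69 and 0.24, adjusted p = 1 for each). ITGAM rose 10.5-fold (3.39 ± 0.65, adjusted p = 0.00669). DHRS3 and ITGAM were likewise called in 5 lines and not in Kasumi1 (0.85 and 0.90, adjusted p = 1 for both), and TGM2 was not called in HL60 (adjusted p = 0.0971) and too low to be tested in Kasumi1. HIC1 and CD38 were called in all 6 lines. Genes that fell across lines included TCEA3 (-3.80 ± 0.80), SPNS3 (-3.79 ± 0.91), the transcription factor gene ZBTB16 (-3.68 ± 1.08, adjusted p = 0.0461), PLXND1 (-3.64 ± 0.72), SEMA4A (-3.60 ± 0.79) and the cytokine gene OSM (-3.13 ± 0.79). None of these falls was called in Kasumi1, and 0 genes were called lower in all 6 lines by edgeR. MYC (chromosome 8, 127735434 to 127741434, plus strand) fell to 0.227 of the DMSO level (-2.14 ± 0.54, adjusted p = 0.0239). In MOLM13 it was not called (-0.68, adjusted p = 0.259). The haematopoietic factor gene GATA2 (-2.97 ± 0.76, adjusted p = 0.0248) and BCL2 (-2.28 ± 0.61, adjusted p = 0.0303) fell, and none of the 3 was called in Kasumi1 (-0.09, -0.30 and -0.02, adjusted p = 1 for each). KDM1A (-0.40 ± 0.15, adjusted p = 0.111), CD86 (0.38 ± 0.83, adjusted p = 0.82) and GFI1B (-1.95, adjusted p = 0.654) were not called.

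Of 21 retinoic acid response genes, 11 were called higher with ATRA (14 adjusted over the list alone). Of the 26 lists, only this list passed with an estimated correlation (median 2.00, adjusted p = 1.44e-10, and adjusted p = 0.021 with an estimated correlation). Antigen presentation genes rose in 5 of 22 cases (7 adjusted over the list alone), among them B2M (0.91), TAP1 (0.99) and HLA-DMB (5.01 ± 0.96), with adjusted p = 2.02e-06 for the list (adjusted p = 0.21 with an estimated correlation). The interferon response list had 8 of 30 members higher (15 adjusted over the list alone), such as IFIT5 (2.90 ± 0.61), with adjusted p = 1.61e-06 (adjusted p = 0.466 with an estimated correlation). Dendritic cell genes had 4 of 11 higher, CD209 (4.34 ± 0.44), CD1A, CD1C and FLT3 (list adjusted p = 0.00525, and adjusted p = 0.21 with an estimated correlation). Of 9 anti-apoptotic genes 6 were higher, including XIAP (0.81 ± 0.16) and MCL1 (0.73 ± 0.19), and 1, BCL2, was lower (list adjusted p = 0.000538, and adjusted p = 0.0889 with an estimated correlation). The pro-apoptotic list had 5 of 24 higher (list adjusted p = 0.0112, and adjusted p = 0.402 with an estimated correlation). Myeloid surface markers (2 of 18 higher, list adjusted p = 0.00812), specific and gelatinase granule proteins (CEACAM1 of 9 higher, 0.00606), inflammatory cytokines and receptors (CCR1 and ICAM1 higher, OSM and IL1RN lower of 25, 0.0272) and NADPH oxidase (NCF1 of 6 higher, 0.0391) also lay higher. Their adjusted p was 0.459, 0.0889, 0.466 and 0.466 with an estimated correlation.

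Lower with ATRA lay MYC and ribosome biogenesis (5 of 23 lower, 18 adjusted over the list alone, median -0.60, list adjusted p = 1.3e-10), integrated stress response (0 of 14, 5 adjusted over the list alone, 0.00231), histones (0 of 10, 0.00642), megakaryocyte and erythroid genes (ITGA2B of 9, 0.0112) and azurophil granule proteins (2 of 10, 0.034). With an estimated correlation these lists had adjusted p = 0.255, 0.466, 0.466, 0.0889 and 0.466. The azurophil calls, ELANE (-1.66, adjusted p = 0.0351) and CTSG (-2.62, adjusted p = 0.0499), and that of the list ended with the GC and length correction (adjusted p = 0.0689, 0.0557 and 0.0641), as did that of the spermidine synthase gene SRM (0.0101 to 0.059). Neutrophil function (3 of 13 higher, adjusted p = 0.138), monocyte and macrophage (2 of 22, CD1D and CCR2, 0.285) and myeloid transcription factors (3 of 18, BATF2, EGR3 and BHLHE40, 0.221) did not pass. Nor did stem and progenitor (GATA2 lower of 17, 0.403), LSD1 complex (HDAC1 higher of 15, 0.425), cell cycle (0 of 30, 0.11) or cell cycle inhibitors (BTG2 of 13, 0.11). The same held for mast cell, basophil and eosinophil (CCR3 higher and 4 lower of 11, 0.266), lymphoid (0 of 13, 0.612), heat shock and unfolded protein response (0 of 12, 0.156) and mitochondrially encoded genes (0 of 13, 0.459). In the lymphoid list the median (0.05) and mean (0.13) had the opposite sign to the test. Over all genes 1731 were called, 1008 higher and 723 lower, 405 without THP1. DESeq2 called 3025.

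**Figure D3:**
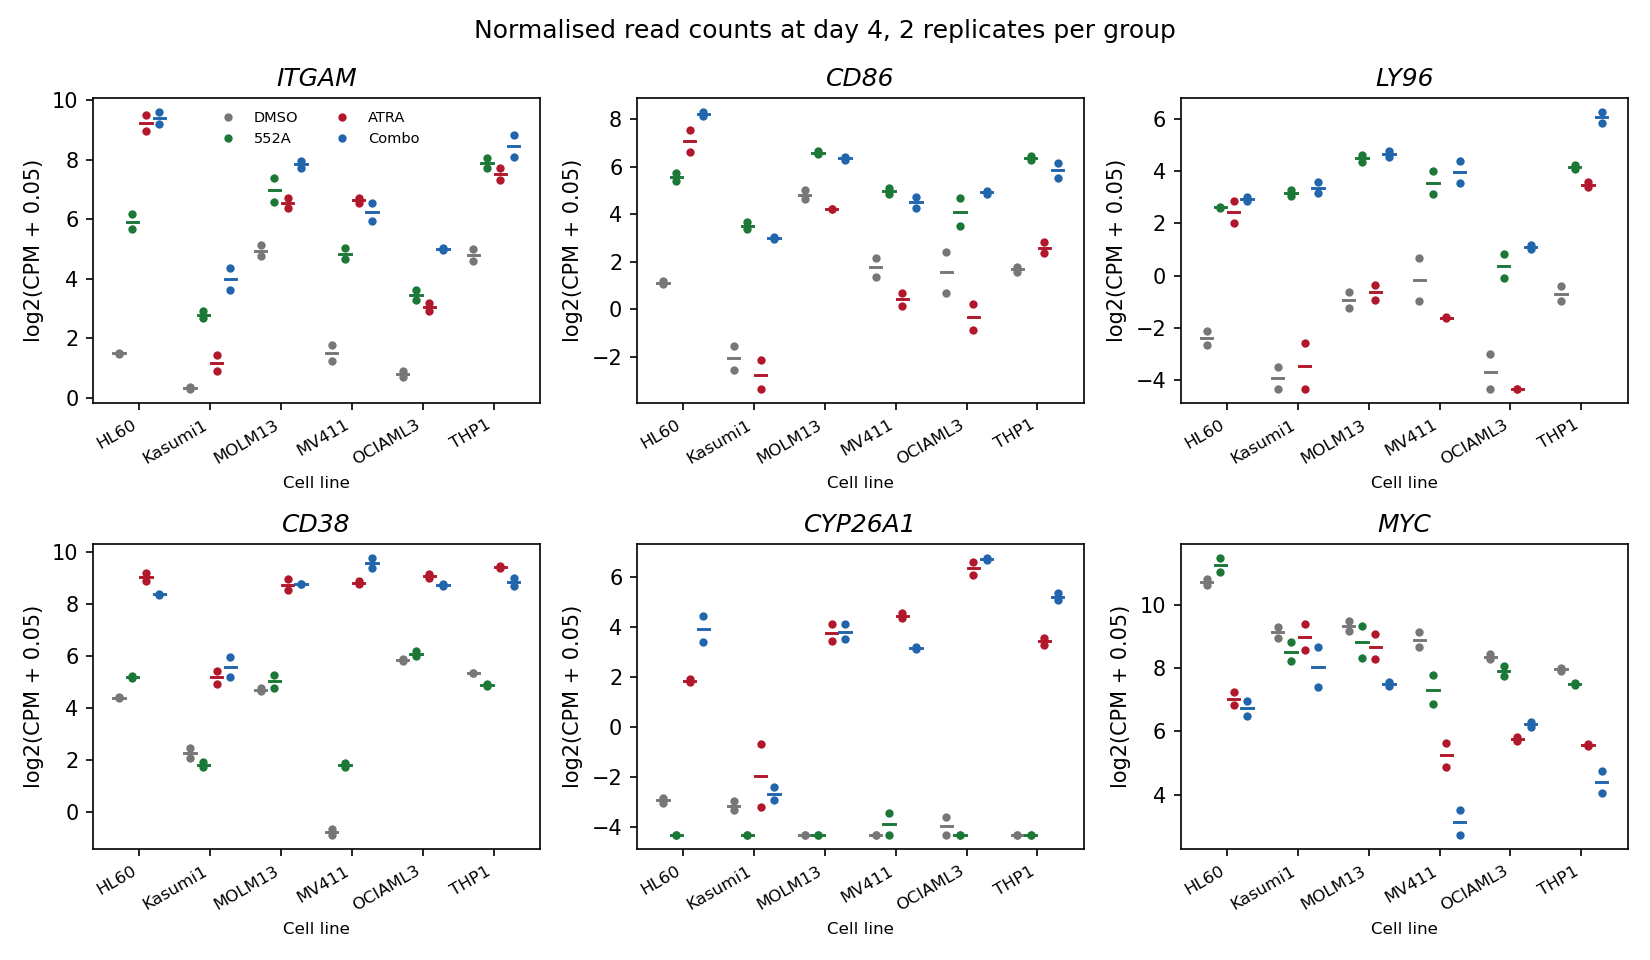
Normalised read counts at day 4 (y axis, log2 of CPM + 0.05) of 6 genes in each cell line (x axis), with a point per replicate and a bar at the mean of 2, coloured by treatment. CD38 in MV411 went from 0.544 CPM with DMSO to 452 with ATRA, and MYC in HL60 from 1670 to 132.

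Lines differed widely in the number of genes that ATRA changed. At day 4 HL60 had 3022 higher and 2740 lower genes, MV411 2303 and 2682, OCIAML3 1714 and 1137, THP1 1762 and 1072, MOLM13 956 and 653, and Kasumi1 16 and 3. Corrected for GC content and length these were 3716 and 3969 in HL60, 4083 and 3395 in MV411, 2989 and 2492 in OCIAML3, 2767 and 3114 in THP1, 1515 and 1364 in MOLM13 and 39 and 12 in Kasumi1, so the majority turned in HL60, MV411 and THP1. In Kasumi1 508 genes had an unadjusted p under 0.05, DESeq2 called 40, and the count fell to 2 without DMSO day 4 replicate 1. Its called genes included MN1 (0.0495 to 3.5 ± 0.416 CPM) and UPB1 (5.09 ± 0.75, adjusted p = 0.0224), higher, and MYCN (-1.97 ± 0.27, adjusted p = 0.0165) and IL6R (-1.38 ± 0.21, adjusted p = 0.0353), lower. CD38 in Kasumi1 went from 4.81 ± 0.902 to 36.8 ± 9.01 CPM. HL60 gained the adhesion receptor gene ADGRE3 (0 to 246 ± 21.2 CPM, at least 4070-fold) and DAAM2 (at least 2410-fold). It lost SPNS3 (224 ± 72.3 to 0.0876 CPM) and TCEA3 (at least 197-fold lower). MOLM13 gained AIPL1 (at least 267-fold) and CYP26A1 (at least 166-fold). It lost the tryptase gene TPSB2 (at least 86.4-fold lower) and the pseudogene BTBD6P1 (5.35 ± 0.153 to 0.0241 CPM). MV411 gained the lipid antigen gene CD1C (0 to 81.8 ± 17.7 CPM, at least 1350-fold) and DHRS3 (12.25 ± 0.42, adjusted p = 3.74e-09). It lost the transcription factor gene BCL11A (-8.08 ± 0.38) and IGLL1 (4.38 ± 0.902 to 0.0195 CPM). OCIAML3 gained CYP26A1 (0.0167 to 82.6 ± 20.3 CPM) and MPPED1 (at least 306-fold). It lost STC2 (14.3 ± 1.77 to 0.0244 CPM) and the potassium channel gene KCNN4 (-7.33 ± 1.05). THP1 gained the prostaglandin synthase gene PTGES (at least 337-fold) and ST6GALNAC5 (0.0251 to 79.6 ± 5.06 CPM), while CSPG4 (-4.21 ± 0.77) and DUSP27 (-3.69 ± 0.30) fell. Of the interferon response genes, ATRA raised 26 of 30 in MV411, 25 of 29 in OCIAML3 and 14 of 22 in HL60. It raised 6 and lowered 2 of 29 in THP1, lowered 6 of 30 in MOLM13, and called 0 of 28 in Kasumi1. The 6 genes called higher with ATRA in all 6 lines were CD38, CCR1, UBASH3B, JCAD, HIC1 and AC011899.2.

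The combination had more called genes across lines than either agent, 5643 against 95 with 552A and 1731 with ATRA. At day 4 HLA-DMB rose 265-fold against DMSO (log2 8.05 ± 0.97, adjusted p = 0.000124) and CHST15 197-fold (7.63 ± 1.06, adjusted p = 0.000281). CD1C rose 176-fold (7.46 ± 1.63, adjusted p = 0.00391) and the guanylate-binding protein gene GBP1 151-fold (7.23 ± 1.21, adjusted p = 0.000747). LY96 rose 52.1-fold (5.70 ± 0.91, adjusted p = 0.000577). ITGAM rose 18.3-fold (4.19 ± 0.64, adjusted p = 0.000461) and reached 691 ± 133 CPM in HL60 and 365 ± 130 in THP1. CD38 rose 18.9-fold (4.24 ± 0.69, adjusted p = 0.000633) and CD86 10.2-fold (3.35 ± 0.79, adjusted p = 0.00623). The cathepsin G gene CTSG fell across lines (-5.06 ± 0.89, adjusted p = 0.00102), and went from 1880 ± 247 to 26.9 ± 8.59 CPM in THP1. It was followed by ZBTB16 (-3.98), SPNS3 (-3.67), S1PR3 (-3.61), TCEA3 (-3.57) and SEMA4A (-3.55 ± 0.78). MYC fell to 0.127 of the DMSO level (-2.98 ± 0.55, adjusted p = 0.00133) and from 484 ± 115 to 9.04 ± 3.49 CPM in MV411. GFI1B, a partner of LSD1, was called (5.14 ± 1.61, adjusted p = 0.031) on 918 counts over all lines with Combo and 8 with DMSO, and of the 2 lines in which it could be tested alone it was higher in 1 and lower in 1. KDM1A was not called (-0.41 ± 0.15, adjusted p = 0.0568), except without OCIAML3 (-0.52).

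With Combo 12 of 22 antigen presentation genes rose (17 adjusted over the list alone), such as HLA-DRA (5.18 ± 0.74) and HLA-DRB1 (3.86). So did 11 of 21 retinoic acid response genes (13 higher and 1 lower adjusted over the list alone), 7 of 18 myeloid surface markers (10) and 6 of 11 dendritic cell genes (8), with BATF3 lower (-1.90). Monocyte and macrophage genes had 9 of 22 higher and 1 lower, with CD163 at 3.91 ± 0.71 and CD1D at 5.01 ± 0.85. These 5 lists passed with adjusted p = 2.26e-06, 2.26e-06, 0.00168, 0.00477 and 0.00726, and had adjusted p = 0.197, 0.0919, 0.256, 0.197 and 0.253 with an estimated correlation. Anti-apoptotic genes (6 of 9 higher, 1 lower, BIRC3 3.31 ± 0.68, list 0.00854), inflammatory genes (6 higher, 2 lower of 25, list 0.0296) and pro-apoptotic genes (7 higher, 1 lower of 24, list 0.0413) also passed, with adjusted p = 0.197, 0.491 and 0.408 with an estimated correlation.

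Among the lists that lay lower with Combo, MYC and ribosome biogenesis had 21 of 23 members lower (23 adjusted over the list alone), including SRM (-1.58 ± 0.21), BOP1 (-1.47), CAD (-1.30) and RRP12 (-1.24), with adjusted p = 1.52e-13 (adjusted p = 0.197 with an estimated correlation). The integrated stress response list had 8 of 14 lower, with the serine synthesis genes PHGDH (-3.06 ± 0.55) and PSAT1 (-2.59 ± 0.53), TRIB3 (-3.31 ± 0.70) and ATF4 (-0.98 ± 0.18), and adjusted p = 2.53e-06 (adjusted p = 0.198 with an estimated correlation). Azurophil granule proteins had 6 of 10 lower, with MPO (-2.79 ± 0.72), PRTN3 (-2.54 ± 0.47) and ELANE (-2.54 ± 0.49), and adjusted p = 3.82e-05 (adjusted p = 0.197 with an estimated correlation). Of 30 cell cycle genes 7 were lower, with CDT1 at -2.19 ± 0.39 and MCM2 at -1.22 ± 0.35, and adjusted p = 2.26e-06 (adjusted p = 0.48 with an estimated correlation). Histones (9 of 10 lower, list 7.82e-05) and megakaryocyte and erythroid genes (2 of 9 lower, ITGA2B and GP9, list 0.00185) had adjusted p = 0.348 and 0.076 with an estimated correlation. The calls of the 4 histone genes with the smallest p ended with the GC and length correction (HIST1H2BK -1.08, 0.00979 to 0.115). The stem and progenitor list had 3 higher, SOX4 (1.81 ± 0.34), MEIS1 (0.88) and CD34 (1.25, 0.0528 with the GC and length correction), and 3 lower of 17, and did not pass (0.873).

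With Combo, specific and gelatinase granule proteins (4 of 9 higher, adjusted p = 0.0964), neutrophil function (4 of 13, with FPR1 at 3.64 ± 0.74, 0.332) and NADPH oxidase (NCF1, 0.326) did not pass. Myeloid transcription factors (3 of 18 higher, 0.226) passed only with the GC and length correction (0.0263). Interferon response (2 of 30 higher, 0.0751), cell cycle inhibitors (RB1 0.93 ± 0.15 and BTG2 2.36, 0.326) and the LSD1 complex (GFI1B higher and ZMYM3 lower, 0.932, with a median of 0.10 and a test in the other direction) did not pass. The remaining lists that did not pass were mast cell, basophil and eosinophil (CCR3 higher and PRG2 lower, 0.326), lymphoid (GZMA and GNLY, 0.76), heat shock and unfolded protein response (0.584) and mitochondrially encoded genes (0.932). Over all genes 5643 were called, 3083 higher and 2560 lower, and 3431 without THP1. Within lines Combo at day 4 gave 2852 higher and 2677 lower genes in HL60, 1242 and 605 in Kasumi1 (1579 and 1915 corrected for GC content and length), 1552 and 1135 in MOLM13, 2446 and 2631 in MV411, 1964 and 1011 in OCIAML3 (2658 and 2722 corrected) and 3745 and 3352 in THP1. The Kasumi1 count of 1847 was 6372 without Combo day 4 replicate 2 and 582 without DMSO day 4 replicate 1. All 30 cell cycle genes were called lower in THP1, against 7 in OCIAML3, 3 in MV411 and 2 in HL60. Interferon response genes higher and lower with Combo were 13 and 1 in HL60, 17 and 0 in Kasumi1, 2 and 5 in MOLM13, 2 and 8 in MV411, 13 and 1 in OCIAML3 and 18 and 2 in THP1.

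**Figure D4:**
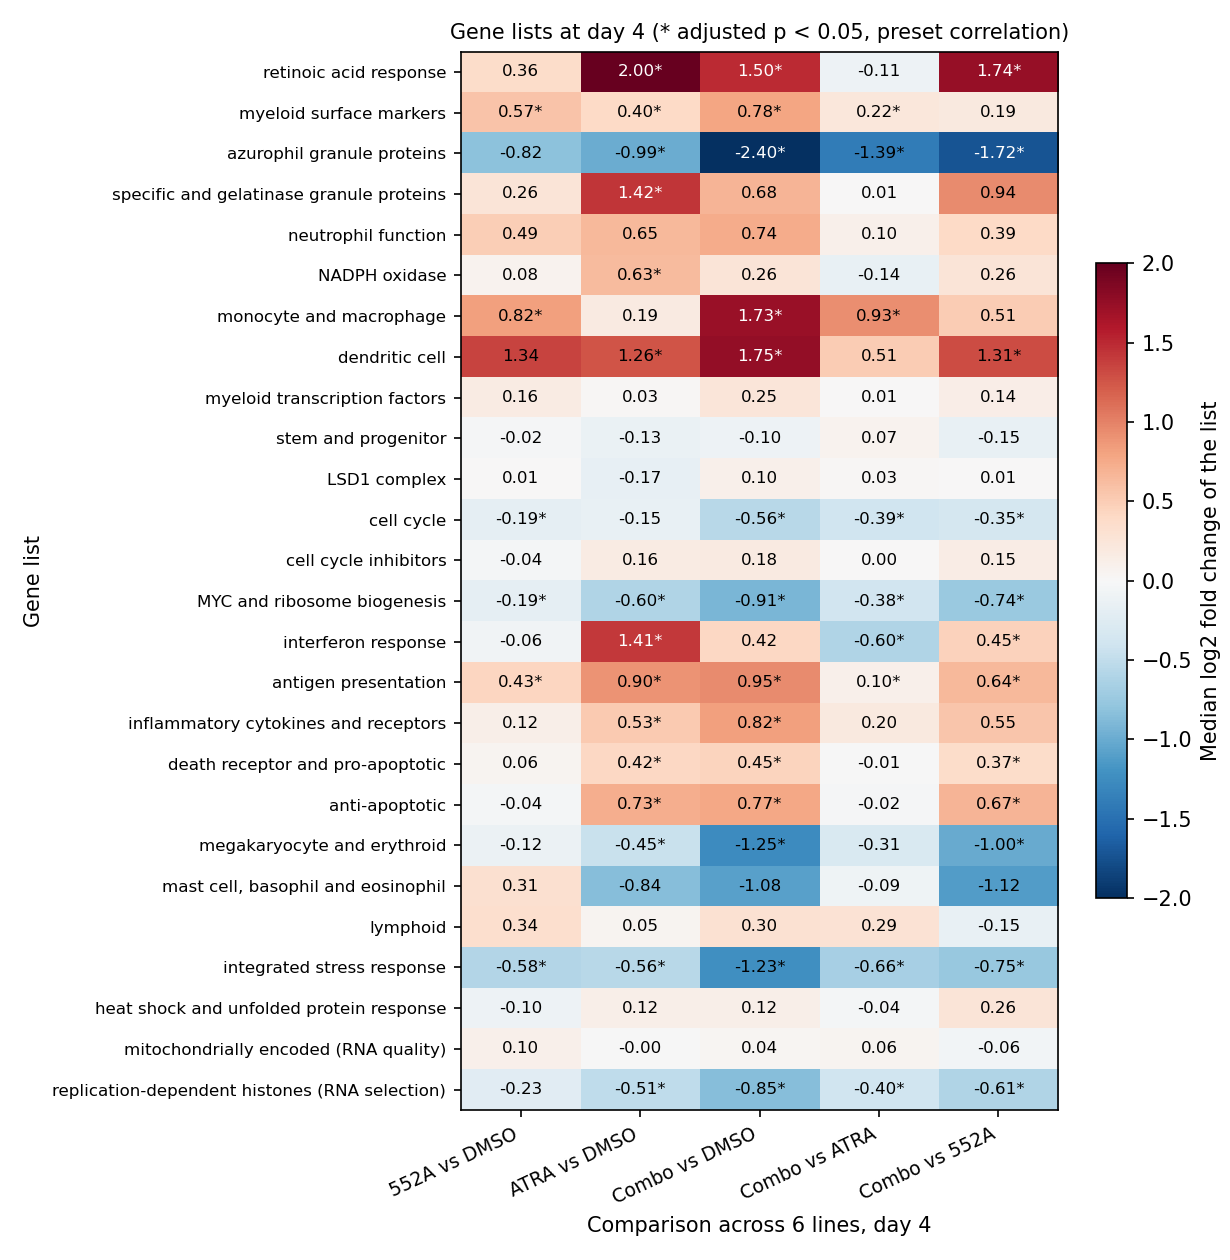
Median log2 fold change of each of the 26 gene lists (y axis) in 5 comparisons across lines at day 4 (x axis), with colour from -2 to 2 and an asterisk at an adjusted p under 0.05 with the preset correlation. Retinoic acid response had a median of 2.00 with ATRA, and azurophil granule proteins of -2.40 with Combo.

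Adding 552A to ATRA raised a small set of genes across lines. At day 4, against ATRA alone, CD163 rose 37.9-fold (log2 5.24 ± 0.77, adjusted p = 0.00713), and of the 4 lines tested it was called in OCIAML3 and THP1 and not in MOLM13 (adjusted p = 0.235) or MV411 (0.696). The cell-surface gene MPZL1 rose 5.61-fold (2.49 ± 0.44, adjusted p = 0.0151). The mitochondrial calcium channel gene MCUB rose 4-fold (2.00 ± 0.39, adjusted p = 0.0329) and SP140 3.44-fold (1.78 ± 0.29, adjusted p = 0.0118). PLEKHA1 (1.60 ± 0.27), KIAA1147 (1.59 ± 0.27) and SCD5 (2.84-fold) rose as well. CLTCL1 fell (-1.06 ± 0.14, adjusted p = 0.00684). ITGAM (0.80 ± 0.57, adjusted p = 0.64), CD86 (2.97 ± 0.81, adjusted p = 0.148, called in 5 lines, and across lines by DESeq2 at 3.13 and without HL60 at 3.86), CD38 (0.08, adjusted p = 0.974), MYC (-0.85, adjusted p = 0.577) and KDM1A (-0.01, adjusted p = 0.986) were not called. In total 66 genes were called, 61 higher and 5 lower, but 0 without MOLM13 and 121 without HL60. With all lines, 2444 genes had an unadjusted p under 0.05 by edgeR and DESeq2 called 395. Monocyte and macrophage genes (2 higher, 9 adjusted over the list alone, list 0.00633), antigen presentation (0, 10 adjusted over the list alone, 0.007) and myeloid surface markers (0, 1 adjusted over the list alone, 0.0497, and 0.0557 with the GC and length correction) lay higher. They had adjusted p = 0.449, 0.685 and 0.685 with an estimated correlation. Azurophil granule proteins (median -1.39, 1.41e-06), cell cycle (-0.39, 6.54e-09), MYC and ribosome biogenesis (-0.38, 1.41e-06), interferon response (-0.60, 0.000212), integrated stress response (-0.66, 2.08e-05) and histones (-0.40, 0.00274) lay lower with 0 members called by edgeR. They had adjusted p = 0.293, 0.618, 0.618, 0.78, 0.532 and 0.685 with an estimated correlation. Of the interferon response genes, 29 were called lower with Combo than with ATRA in MV411 and 14 in OCIAML3, and 16 were called higher in Kasumi1 and 10 in THP1. Without the libraries that stood apart by GC trend these counts were 26, 20, 13 and 14. Whether the list differed between lines was not tested.

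Within lines, Combo against ATRA at day 4 gave 138 higher and 117 lower genes in HL60, 913 and 341 in Kasumi1 (1400 and 1517 corrected for GC content and length), 571 and 402 in MOLM13, 2112 and 1584 in MV411 (2538 and 3338 corrected), 296 and 134 in OCIAML3 (578 and 526 corrected) and 1519 and 1532 in THP1. The MV411 count of 3696 was 1516 without Combo day 4 replicate 2 and 6309 without Combo day 4 replicate 1. LYZ, GCNT2, PRDX1 and CAMSAP2 were called higher in all 6 lines.

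Adding ATRA to 552A brought the retinoic acid targets. Against 552A alone at day 4, CHST15 rose 115-fold (log2 6.84 ± 1.01, adjusted p = 0.00233), HIC1 32.7-fold (5.03 ± 0.68, adjusted p = 0.00146) and CD38 17.2-fold (4.11 ± 0.68, adjusted p = 0.00479). CEACAM1 (4.94 ± 0.99), DHRS3 (4.75 ± 1.03) and SYT2 (4.63 ± 0.70) rose as well. CYP26A1 was called (adjusted p = 4.33e-05), with 1 count over all lines with 552A and 8191 with Combo. CTSG (-4.14 ± 0.87), the membrane protein gene EMP1 (-3.87 ± 0.79), TCEA3 (-3.57 ± 0.77), STC2 (-3.22 ± 0.84), SEMA4A (-3.19 ± 0.76), MPO (-3.04 ± 0.75), CD163 (-2.65 ± 0.54) and MYC (-2.56 ± 0.55, adjusted p = 0.0116) fell. In Kasumi1 CHST15, HIC1, CD38 and SYT2 were called, CEACAM1, DHRS3 and the genes that fell were not, and CYP26A1 and CD163 were too low to be tested. ITGAM (1.42 ± 0.57, adjusted p = 0.127), CD86 (-0.09, adjusted p = 0.956) and KDM1A (-0.35, adjusted p = 0.159) were not called. The lists that lay higher were retinoic acid response (9 of 21 called, 11 adjusted over the list alone, list 7.39e-08), antigen presentation (4 of 22, 8, list 5.57e-05), anti-apoptotic (5 of 9, list 0.000314), dendritic cell (1 of 11, list 0.00862), interferon response (0 of 30, list 0.00991) and pro-apoptotic (2 of 24, list 0.0107). They had adjusted p = 0.0596, 0.263, 0.0913, 0.263, 0.605 and 0.302 with an estimated correlation. Lower lay MYC and ribosome biogenesis (15 of 23 called, 23 adjusted over the list alone, list 3.02e-14), azurophil granule proteins (4 of 10, list 5.57e-05), cell cycle (CDT1 of 30, list 0.000136), histones (0 of 10, list 0.000246), integrated stress response (3 of 14, list 0.000565) and megakaryocyte and erythroid (ITGA2B of 9, list 0.00257). These lists had adjusted p = 0.213, 0.167, 0.554, 0.395, 0.361 and 0.0596 with an estimated correlation. The calls of PRTN3, ELANE and CDT1 ended with the GC and length correction (adjusted p = 0.139, 0.162 and 0.061). In total 1800 genes were called, 900 in each direction, and 369 without THP1. Within lines the counts were 5453 in HL60, 26 in Kasumi1 (22 higher and 4 lower, 43 and 24 corrected for GC content and length, and 2880 without Combo day 4 replicate 2), 1784 in MOLM13, 2764 in MV411, 1921 in OCIAML3 (1297 and 624, 1908 and 1990 corrected) and 4971 in THP1.

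No gene had a Combo effect at day 4 that differed, after adjustment, from the sum of the single-agent effects on the log2 scale. By edgeR 0 of 24199 genes were called, 215 had an unadjusted p under 0.05, and DESeq2 called 42. In simulated data the same test recovered 80% and 88% of genes changed by 2 and -2 (log2) and 34% and 18% at 1 and -1. Recovery may be lower for genes low with DMSO or with effects that differ between lines. The interferon response (median -0.85, adjusted p = 7.51e-05), azurophil granule (-0.56, 0.000247), cell cycle (-0.19, 0.000691), neutrophil function (-0.51, 0.0154), MYC and ribosome biogenesis (-0.17, 0.0308, and 0.062 with the GC and length correction) and myeloid surface marker (-0.27, 0.0373) lists lay below the sum. They had adjusted p = 0.772, 0.772, 0.905, 0.772, 0.905 and 0.772 with an estimated correlation. The cell cycle list turned to the other direction without THP1 (adjusted p = 0.823).

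Changes at day 2 resembled those at day 4 in direction. Genes called at both days in the same direction within a line numbered 128 for 552A in HL60, 582 in Kasumi1, 196 in MOLM13, 307 in MV411, 294 in OCIAML3 and 877 in THP1, and 0 were called in opposite directions. For ATRA they numbered 3772, 8, 406, 1099, 1740 and 2042, with 23, 0, 0, 11, 1 and 0 opposite. At day 2, 552A gave 230 higher and 13 lower genes in HL60, 582 and 54 in Kasumi1, 219 and 49 in MOLM13, 271 and 74 in MV411, 309 and 84 in OCIAML3 and 986 and 342 in THP1. Corrected for GC content and length these were 331 and 62, 969 and 349, 406 and 188, 758 and 462, 421 and 314, and 1357 and 1744. Without 552A day 2 replicate 1 the counts were 9317 in OCIAML3 and 7301 in THP1, the lines whose 552A day 2 replicate 2 stood apart by GC trend. ATRA at day 2 gave 5685 called genes in HL60, 8 in Kasumi1, 478 in MOLM13, 1296 in MV411, 2568 in OCIAML3 and 2927 in THP1 (1768 higher and 1159 lower, 2477 and 3595 corrected). Combo at day 2 gave 7551, 688 (570 and 118, 1130 and 539 corrected), 1359 (892 and 467, 1432 and 1282 corrected), 3548, 2606 (1750 and 856, 3030 and 2694 corrected) and 5730. Across lines at day 2, 472 of 24130 genes were called with 552A (182 without the 5 libraries that stood apart, 91 without THP1), 2261 with ATRA (171 without THP1) and 6564 with Combo. The 552A and ATRA effects differed between days for 0 of 26382 genes by edgeR (1106 and 2299 at an unadjusted p under 0.05, and 0 and 15 called by DESeq2). For Combo 3 genes were called, 0 without HL60 and 11 without Kasumi1. With limma-voom 1 gene was called, and swapping the days within lines gave up to 5, so chance was not excluded. The 3 genes, all lower at day 4 relative to day 2, were the Src-family kinase gene FGR (-1.24 ± 0.20, adjusted p = 0.025), the cystatin gene CST7 (-1.28 ± 0.21, adjusted p = 0.025) and ADGRG3 (-2.52 ± 0.36, adjusted p = 0.0187). DESeq2 called 31, and with the GC and length correction 1 gene was higher and 7 were lower.

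Effects differed between lines for 1331 of 23385 genes with 552A (5.7%), 7339 with ATRA (31.4%) and 7861 with Combo (33.6%) at day 4, by the F test of the line-by-treatment terms. With the GC and length correction these were 3638 (15.6%), 11485 (49.1%) and 12284 (52.5%). The CD38 response to ATRA differed (adjusted p = 4.16e-14), with 0.544 ± 0.0658 to 452 ± 32.1 CPM in MV411, and so did the MYC response (adjusted p = 7.2e-06), with 1670 ± 151 to 132 ± 26.7 CPM in HL60. The LYZ response to 552A differed (adjusted p = 2.74e-15), from a log2 change of 6.92 in HL60 to 1.59 in MOLM13. CD86 rose with ATRA in HL60 from 2.12 ± 0.153 to 145 ± 63.3 CPM, while in Kasumi1 it rose with 552A from 0.208 ± 0.127 to 11.5 ± 1.54 CPM, and its response differed between lines for ATRA (adjusted p = 9e-10) and 552A (adjusted p = 0.000397). HLA-DMB with 552A did not differ between lines after adjustment (adjusted p = 0.349).

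Within lines, genes called with both 552A and ATRA at day 4 in the same direction numbered 99 in HL60, 3 in Kasumi1, 82 in MOLM13, 396 in MV411, 214 in OCIAML3 and 636 in THP1. Independent lists of these sizes would share 27.4, 0.7, 14.2, 120.4, 41.1 and 106.5. Unchanged groups simulated against the same DMSO libraries shared 0 on average (0.07 in Kasumi1). Those groups held no true change, so hardly any gene could be called in either. Their shared count therefore cannot show how much the shared controls add when many genes are called. Genes called in opposite directions numbered 26, 3, 37, 148, 69 and 100. The covariance of the fold changes exceeded its simulated value by 0.1285 in HL60, 0.0584 in MOLM13, 0.2085 in MV411, 0.1146 in OCIAML3 and 0.2623 in THP1, and was below it in Kasumi1 (-0.0108). The correlation of the fold changes across genes lay below its simulated value in all 6 lines, at 0.26 against 0.497 in HL60, 0.294 against 0.49 in Kasumi1, 0.277 against 0.538 in MOLM13, 0.275 against 0.481 in MV411, 0.295 against 0.473 in OCIAML3 and 0.455 against 0.559 in THP1. Effects of 1 drug alone lower this correlation, so its distance from the simulated value does not measure the overlap. The controls were not split, since each part would hold 1 DMSO library a line, and part of the excess of shared calls may come from the shared controls.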

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

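The tests chosen after the result was seen were the GC content test of the replicate axis, the mislabelling, spread and GC tests of the Kasumi1 pattern, the GC test of the 552A pattern, and the swaps of labels for 552A and ATRA against DMSO at both days. Among 84 sets of 6 lines, 8 had 1 line far from the other 5, and chance gives this in about 1 in 20 sets. THP1 had 1328 called genes with 552A at day 2, against 243 to 636 in the other lines, and 751 without its replicate 2, whose GC trend stood apart. SPNS3 in HL60 had a log2 change of -9.365 with Combo, and the other lines ran from -4.157 to -1.717. MCUB in MV411 was at 3.895 for Combo against ATRA, and the other lines ran from 1.388 to 2.028. CD86 in HL60 was at 5.984 with ATRA, and the other lines ran from -2.007 to 0.849. CD38 in MV411 was at 9.732 with ATRA (others 2.953 to 4.543), 10.471 with Combo (others 2.865 to 4.041) and 7.821 for Combo against 552A (others 2.585 to 3.965). ITGAM in HL60 was at 3.426 for Combo against 552A, and the other lines ran from 0.611 to 1.491.

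The effect at day 4 differed between lines, by the F test of the line-by-treatment terms, for 1331 genes with 552A, 7339 with ATRA and 7861 with Combo, and for 3638, 11485 and 12284 with the GC and length correction. Of 52 effects of named genes tested, 39 differed. With 552A the adjusted p was 2.74e-15 for LYZ, 1.74e-05 for GCNT2, 0.0106 for SP140, 0.00512 for ITGAM, 0.000397 for CD86 and 1.65e-06 for CD38. With ATRA it was 2.92e-11 for DHRS3, 8.1e-05 for CHST15, 8.28e-11 for SYT2, 0.0132 for HIC1, 3.88e-15 for CD1D, 3.43e-08 for TCEA3, 1.19e-06 for SPNS3 and 7.1e-08 for ZBTB16. It was 3.85e-05 for PLXND1, 2.96e-11 for SEMA4A, 6.96e-05 for OSM, 4.21e-06 for KDM1A, 0.000491 for CYP26A1, 7.5e-12 for ITGAM, 9e-10 for CD86, 4.16e-14 for CD38 and 7.2e-06 for MYC. With Combo it was 5.41e-06 for CHST15, 3.27e-08 for CD1C, 0.000231 for GBP1, 0.00779 for LY96, 9.73e-11 for CTSG, 6.09e-08 for ZBTB16, 5.7e-06 for SPNS3 and 2.82e-11 for S1PR3. It was 5.76e-09 for TCEA3, 2.25e-11 for SEMA4A, 4.11e-05 for KDM1A, 5e-04 for CYP26A1, 5e-09 for ITGAM, 2e-07 for CD86, 4.81e-15 for CD38 and 6.46e-07 for MYC. The Combo effect was called as different between days for FGR (log2 -1.243), CST7 (-1.281) and ADGRG3 (-2.52), but for 0 genes without HL60, and chance was not excluded by the swaps of days given below.

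Replicates of a group differed mainly along 1 axis, which held 73.9% of their variance. Its loadings correlated with gene GC content at r = -0.899 across genes, and the RN7S ratio of the replicates followed it over the 48 groups (Pearson r = -0.941, permutation p = 1e-05, the smallest that the permutations can give). A GC bias of single libraries may therefore underlie the axis, and its origin is not known. A difference in library size stays open (Pearson r = -0.304 over 48 groups, permutation p = 0.036), since r was -0.241 without the 2 farthest groups and ran from -0.642 to 0.176 within lines. No biological explanation was tested, since the replicates of a group share their line, treatment and day.

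With ATRA at day 4 Kasumi1 had 19 called genes, from 2 without DMSO day 4 replicate 1 to 27 without Combo day 4 replicate 1. A GC and length bias as the whole cause was argued against by 51 called genes after the correction, and a larger spread by a median difference between replicates of 0.169, against 0.157 to 0.29 in the other lines. Against mislabelled ATRA libraries, Combo against 552A, which uses other libraries, called 26 genes, and retinoic acid response members were called higher with ATRA at day 2 (1 of 15) and day 4 (2 of 15), although CYP26A1, called in the other 5 lines, was too low to be tested in Kasumi1 with ATRA (0.317 ± 0.366 CPM) and in the separate Combo libraries (0.11 ± 0.038). That count was 2 without 552A day 4 replicate 1, 3 without 552A day 4 replicate 2 and 67 with the GC and length correction, but 2880 without Combo day 4 replicate 2, which leaves the Combo library with the GC trend. As a hypothesis, Kasumi1 may respond to ATRA in the same direction but less. There 70.6% of 564 genes shared by at least 4 of the other lines had their direction (median log2 0.115), against 88.1% to 99.1% elsewhere. The GC trend could also give this agreement, which was not recomputed with the correction.

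Of the 95 genes called across lines with 552A at day 4, 92 were higher. A GC and length bias was argued against by 97% higher among the calls after the correction, although within lines the corrected calls were nearer to even in THP1 (1930 higher and 1589 lower) and MV411 (1392 and 1247). That genes near zero can only rise was argued against by 96.2% higher (50 of 52) among called genes with a DMSO mean of at least 1 CPM. The count of called genes was 27 without MOLM13. As a hypothesis, LSD1 inhibition may raise more transcripts than it lowers among genes that change across lines at day 4, found and tested on the same data, and less so within THP1 and MV411.

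Swapping the treatment labels within lines gave 32 splits, the real one included. With 552A at day 2 (472 genes, at most 21 in the other splits) and day 4 (95, at most 6), only 1 split, the real one, called as many. So it was with ATRA at day 2 (2261, at most 1355) and day 4 (1731, at most 949), and with Combo at day 2 (6564, at most 2934) and day 4 (5643, at most 1165). The same held for Combo against ATRA (66, at most 4) and Combo against 552A (1800, at most 147). In each, 1 of 32 is the smallest share that these swaps can give, and the comparisons were not adjusted for their number. The swaps therefore argue against chance in each of these comparisons but do not exclude it. The swaps decide nothing for Combo beyond the sum, since with 0 genes for the real labels all 32 splits call as many by edgeR (215 at an unadjusted p under 0.05 with the real labels, and 42 by DESeq2). For the difference between days, tested with limma-voom and swapped days, the swaps likewise decide nothing for 552A and for ATRA, since all 32 splits had 0 genes, the real one included. There edgeR had 1106 and 2299 at an unadjusted p under 0.05 and DESeq2 called 0 and 15. With Combo 10 of 32 had as many as the 1 gene of the real days, with at most 5, so chance cannot be excluded for Combo.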

How the results depend on the processing

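The GC and length correction and the fits without the 5 libraries that stood apart were chosen after seeing the data, and every other setting was fixed before the data were examined. With the size factors of DESeq2 in place of TMM, all 69 counts of called genes and lists stayed within 1.5 times of the values reported, 349 values of named genes and list tests kept their direction and side of the threshold and 3 lost their call. These values were kept and calls were lost for 277 and 11 with the DESeq2 test, 284 and 5 without the filter on low counts, 322 and 30 with the GC and length correction, and 314 and 32 without the 5 libraries. CD86 with 552A at day 4 passed the threshold with DESeq2, without the filter, with unsummed libraries and without HL60. CD86 for Combo against ATRA did so with DESeq2, with unsummed libraries and without HL60. KDM1A with Combo did so with unsummed libraries and without OCIAML3, and RARA with Combo with unsummed libraries and without MV411. Unsummed libraries also gave calls of GFI1B with 552A and for Combo against ATRA, KDM1A with ATRA and for Combo against 552A, and ITGAM for Combo against 552A. Leaving out 1 line or library ended 471 calls of named genes and lists, left 2075 as they were and reversed 1. For the gene list cell cycle, Combo beyond the sum, day 4, adjusted p was 0.823 in the other direction without THP1, 0.000691 with all lines and 6.63e-08 without HL60, and adjusted p = 0.905 with an estimated correlation. With 2 replicates a group, a fit without 1 library leaves a group with a single library, which is assumed to vary like the others. Changes of 2-fold were often missed within a line at this depth and replication, as the simulated recoveries showed. In the values that follow the cause of a change was not tested, except that fewer libraries, lines or residual degrees of freedom, or more genes tested, are part of how the setting was built.

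Without the filter on low counts, 552A at day 2 gave 1023 in HL60, 554 in MOLM13, 720 in MV411, 1071 in OCIAML3 and 2998 in THP1. For 552A at day 4 it was 429 in HL60, 575 in MOLM13 and 1447 in MV411. For ATRA at day 2 it was 34 in Kasumi1, 729 in MOLM13 and 4933 in THP1. For ATRA at day 4 it was 62 in Kasumi1. For Combo in OCIAML3 it was 4142 at day 2 and 4909 at day 4. For Combo against ATRA it was 537 in HL60 and 958 in OCIAML3. For Combo against 552A it was 105 in Kasumi1 and 3786 in OCIAML3. Across lines the filter moved only the day differences by over 1.5 times, to 3 for ATRA and 12 for Combo. With the DESeq2 test, 552A gave 449 in HL60 and 526 in MV411 at day 2 and 339 in HL60 at day 4. By DESeq2 ATRA gave 16 at day 2 and 40 at day 4 in Kasumi1. Combo against ATRA gave 564 in HL60 and 672 in OCIAML3, and Combo against 552A gave 61 in Kasumi1. Across lines DESeq2 gave 1504 for 552A at day 2, 312 for 552A at day 4, 3769 for ATRA at day 2, 3025 for ATRA at day 4, 395 for Combo against ATRA, 3151 for Combo against 552A, 42 for Combo beyond the sum, 15 for the day difference of ATRA and 31 for the day difference of Combo.

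With the GC and length correction, 552A at day 2 gave 393 in HL60, 1318 in Kasumi1, 594 in MOLM13, 1220 in MV411, 735 in OCIAML3 and 3101 in THP1. 552A at day 4 then gave 384 in HL60, 2044 in Kasumi1, 646 in MOLM13, 2639 in MV411, 1069 in OCIAML3 and 3519 in THP1. ATRA at day 2 then gave 17 in Kasumi1, 886 in MOLM13, 2671 in MV411, 5574 in OCIAML3 and 6072 in THP1. ATRA at day 4 then gave 51 in Kasumi1, 2879 in MOLM13, 7478 in MV411, 5481 in OCIAML3 and 5881 in THP1. Combo at day 2 then gave 1669 in Kasumi1, 2714 in MOLM13, 5822 in MV411, 5724 in OCIAML3 and 8985 in THP1. Combo at day 4 then gave 3494 in Kasumi1, 4432 in MOLM13, 7864 in MV411 and 5380 in OCIAML3. Combo against ATRA then gave 829 in HL60, 2917 in Kasumi1, 2045 in MOLM13, 5876 in MV411, 1104 in OCIAML3 and 6041 in THP1. Combo against 552A then gave 67 in Kasumi1, 3303 in MOLM13, 4835 in MV411, 3898 in OCIAML3 and 8134 in THP1. Across lines this correction gave 268 for 552A at day 2, 1420 for ATRA at day 2 and 8 for the day difference of Combo. Genes whose effect differed between lines then numbered 3638 for 552A, 11485 for ATRA and 12284 for Combo. Without the 5 libraries, 552A at day 2 gave 972 in Kasumi1 and 751 in THP1. Their absence with 552A at day 4 gave 1455 in Kasumi1, 193 in MOLM13 and 909 in OCIAML3. Their absence with ATRA at day 2 gave 5197 in OCIAML3 and 5522 in THP1. Their absence with ATRA at day 4 gave 5123 in OCIAML3 and 4429 in THP1. Their absence with Combo at day 2 gave 1107 in Kasumi1 and 5813 in OCIAML3. Their absence with Combo at day 4 gave 1196 in Kasumi1 and 6422 in OCIAML3. Their absence with Combo against ATRA gave 1516 in MV411 and 1161 in OCIAML3. Their absence with Combo against 552A gave 1669 in MV411 and 5351 in OCIAML3. Across lines the counts without these libraries were 182 for 552A at day 2 and 875 for Combo against 552A.

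Libraries of a line with the same replicate number deviated together in some groups and apart in others, so the number was not taken to pair them. Correlations of the deviations of same-numbered libraries from their group means, over the 28 pairs of groups in a line, ran from -0.886 in MV411 to 0.949 in MV411. Their mean was positive in every line, from 0.04 in MOLM13 to 0.337 in THP1, and 12 to 21 of the pairs were over 0.1. With the GC trend removed the mean ran from 0.182 to 0.251 and single correlations from -0.523 to 0.835, so a shared part of the deviations is not excluded. With the replicate number as a replicate block, 552A at day 2 gave 2257 in THP1 and ATRA at day 2 gave 4949 in THP1, and the other 49 counts stayed within 1.5 times. With unsummed libraries and line by replicate number as the replicate block, which counts the replicates of a line as separate, the calls across lines were 3152 for 552A at day 2, 820 for 552A at day 4, 5763 for ATRA at day 2, 5632 for ATRA at day 4, 9373 for Combo at day 4, 1134 for Combo against ATRA, 5827 for Combo against 552A, 200 for the day difference of ATRA and 259 for the day difference of Combo. With no replicate block and the cell line left out of the model of the sums, they were 1 for 552A at day 2, 0 for 552A at day 4, 1 for ATRA at day 2, 0 for ATRA at day 4, 47 for Combo at day 2, 58 for Combo at day 4, 0 for Combo against ATRA and 1 for Combo against 552A, since the differences between lines then entered the spread. With an estimated correlation between the genes of a list, the lists called numbered 0 for 552A, 1 for ATRA, 0 for Combo, 0 for Combo against ATRA, 0 for Combo against 552A and 0 for Combo beyond the sum. With a threshold of 0.01, genes called with both agents in the same direction numbered 57 in HL60, 0 in Kasumi1, 31 in MOLM13, 142 in MV411, 85 in OCIAML3 and 298 in THP1.

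Leaving out each of the 16 libraries of a line in turn gave these lowest and highest counts of called genes, with the library left out. In HL60 552A at day 2 gave 70 without DMSO day 2 replicate 1 and at most 291. In HL60 552A at day 4 gave 56 without DMSO day 4 replicate 2 and at most 225. In HL60 ATRA at day 2 gave 3036 without ATRA day 2 replicate 1 and at most 6503. In HL60 ATRA at day 4 gave 3219 without DMSO day 4 replicate 1 and at most 6459. In HL60 Combo at day 4 gave 3374 without DMSO day 4 replicate 1 and at most 6165. In HL60 Combo against ATRA gave 50 without Combo day 4 replicate 1 and at most 307. In HL60 Combo against 552A gave 3380 without 552A day 4 replicate 1 and at most 6033. In Kasumi1 552A at day 2 gave 191 without DMSO day 2 replicate 1 and 976 without Combo day 4 replicate 2. In Kasumi1 552A at day 4 gave 369 without DMSO day 4 replicate 1 and 1455 without Combo day 4 replicate 1. In Kasumi1 ATRA at day 2 gave 0 without DMSO day 2 replicate 1 and at most 11. In Kasumi1 ATRA at day 4 gave 2 without DMSO day 4 replicate 1 and at most 27. In Kasumi1 Combo at day 2 gave 199 without DMSO day 2 replicate 1 and 1109 without Combo day 4 replicate 2. In Kasumi1 Combo at day 4 gave 582 without DMSO day 4 replicate 1 and 6372 without Combo day 4 replicate 2. In Kasumi1 Combo against ATRA gave 415 without ATRA day 4 replicate 2 and 4802 without Combo day 4 replicate 2. In Kasumi1 Combo against 552A gave 2 without 552A day 4 replicate 1 and 2880 without Combo day 4 replicate 2. In MOLM13 552A at day 2 gave 98 without DMSO day 2 replicate 1 and at most 293. In MOLM13 552A at day 4 gave 93 without DMSO day 4 replicate 1 and at most 296. In MOLM13 ATRA at day 2 gave 227 without DMSO day 2 replicate 1 and at most 532. In MOLM13 ATRA at day 4 gave 585 without DMSO day 4 replicate 1 and at most 1903. In MOLM13 Combo at day 2 gave 733 without DMSO day 2 replicate 1 and at most 1498. In MOLM13 Combo at day 4 gave 1414 without Combo day 4 replicate 2 and at most 3027. In MOLM13 Combo against ATRA gave 348 without Combo day 4 replicate 1 and at most 1136. In MOLM13 Combo against 552A gave 844 without Combo day 4 replicate 1 and at most 1779. In MV411 552A at day 2 gave 100 without DMSO day 2 replicate 2 and at most 409. In MV411 552A at day 4 gave 410 without 552A day 4 replicate 2 and at most 1148. In MV411 ATRA at day 2 gave 586 without ATRA day 2 replicate 1 and at most 1489. In MV411 ATRA at day 4 gave 2761 without ATRA day 4 replicate 2 and at most 5730. In MV411 Combo at day 2 gave 1506 without DMSO day 2 replicate 2 and at most 4465. In MV411 Combo against ATRA gave 1516 without Combo day 4 replicate 2 and 6309 without Combo day 4 replicate 1. In MV411 Combo against 552A gave 1571 without 552A day 4 replicate 2 and at most 3333. In OCIAML3 552A at day 2 gave 87 without DMSO day 2 replicate 2 and 9317 without 552A day 2 replicate 1. In OCIAML3 552A at day 4 gave 184 without DMSO day 4 replicate 2 and 909 without 552A day 2 replicate 2. In OCIAML3 ATRA at day 2 gave 823 without ATRA day 2 replicate 1 and 5197 without 552A day 2 replicate 2. In OCIAML3 ATRA at day 4 gave 1362 without ATRA day 4 replicate 2 and 5123 without 552A day 2 replicate 2. In OCIAML3 Combo at day 2 gave 833 without DMSO day 2 replicate 2 and 5831 without 552A day 2 replicate 1. In OCIAML3 Combo at day 4 gave 1333 without DMSO day 4 replicate 2 and 6442 without 552A day 2 replicate 1. In OCIAML3 Combo against ATRA gave 128 without ATRA day 4 replicate 1 and 1161 without 552A day 2 replicate 2. In OCIAML3 Combo against 552A gave 618 without 552A day 4 replicate 2 and 5386 without 552A day 2 replicate 1. In THP1 552A at day 2 gave 429 without DMSO day 2 replicate 1 and 7301 without 552A day 2 replicate 1. In THP1 552A at day 4 gave 610 without DMSO day 4 replicate 2 and at most 2000. In THP1 ATRA at day 2 gave 1211 without DMSO day 2 replicate 1 and 5546 without 552A day 2 replicate 1. In THP1 ATRA at day 4 gave 1549 without DMSO day 4 replicate 1 and 4446 without 552A day 2 replicate 1. In THP1 Combo at day 2 gave 3602 without Combo day 2 replicate 2 and at most 7140. In THP1 Combo against ATRA gave 1605 without ATRA day 4 replicate 2 and at most 4166. In THP1 Combo against 552A gave 3125 without 552A day 4 replicate 1 and at most 6466.

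Leaving out 1 line at a time moved these results across lines by over 1.5 times. 552A at day 2 ranged from 91 without THP1 to 605 without HL60. ATRA at day 2 ranged from 171 without THP1 to 2927 without Kasumi1. 552A at day 4 ranged from 27 without MOLM13 to 115 without HL60. ATRA at day 4 ranged from 405 without THP1 to 2295 without Kasumi1. Combo at day 4 ranged from 3431 without THP1 to 4756 without HL60. Combo against ATRA ranged from 0 without MOLM13 to 121 without HL60. Combo against 552A ranged from 369 without THP1 to 2070 without Kasumi1. Genes whose Combo effect differed between days ranged from 0 without HL60 to 11 without Kasumi1. Lists called with Combo against ATRA ranged from 5 without THP1 to 11 without MV411. Lists called with Combo beyond the sum ranged from 3 without THP1 to 8 without HL60. The counts of genes whose effect differed between lines stayed within 1.5 times for every day 4 library left out.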

Other observations

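The GC and length correction, and which of the preset lists are given per line here, were chosen after the result was seen. The integrated stress response list, called lower with Combo across lines with a preset correlation (adjusted p = 2.53e-06, and adjusted p = 0.198 with an estimated correlation), had these calls by line at day 4. With Combo 12 of 14 members were called lower in HL60 and in MOLM13, 11 in MV411 and 10 in OCIAML3, with 1 higher there. THP1 had 6 higher and 6 lower, and Kasumi1 had 1 higher and 0 lower by edgeR. With ATRA alone 11 were lower in HL60, 7 in OCIAML3, 5 in THP1, 2 in MOLM13 and 2 in MV411. Heat shock and unfolded protein response genes with ATRA were 6 lower and 0 higher of 12 in HL60, while 3 were higher in MOLM13, 3 in MV411 and 4 in THP1. Cell cycle genes with ATRA were 15 lower and 2 higher of 30 in HL60, 8 lower in OCIAML3 and 3 lower in THP1, and 8 higher in MOLM13. With the GC and length correction the cell cycle genes called lower were 18 in OCIAML3 and 21 in THP1, and 7 were higher in MV411. Whether these lists differed between lines was not tested.

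Dendritic cell genes were called higher with Combo in every line, 9 of 11 in THP1, 8 of 10 in HL60, 6 of 10 in MOLM13 and in MV411, and 4 of 8 in Kasumi1 and in OCIAML3, with 0 to 3 called lower. Neutrophil function genes with ATRA were 8 higher of 11 in HL60 and 6 of 12 in THP1, while MOLM13 had 1 higher and 3 lower of 8. Monocyte and macrophage genes with 552A were 11 higher and 0 lower of 21 in THP1, and with Combo 16 and 2. Anti-apoptotic genes with ATRA were 7 higher of 9 in MV411, 6 in HL60, 5 in THP1, 4 in OCIAML3 and 3 in MOLM13, each with 1 lower. Replication-dependent histone genes were all called lower with Combo in THP1 (10 of 10, and 9 with the GC and length correction), 3 of 10 were lower in MOLM13, and 4 of 10 were higher with ATRA in MV411. Azurophil granule genes with Combo were 8 lower of 10 in MV411, 7 of 9 in HL60, 7 of 10 in MOLM13, 7 of 11 in THP1, 3 of 8 in Kasumi1 and 1 of 10 in OCIAML3, where 2 were higher.

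Of the genes called in the same direction in at least 4 of the other 5 lines at day 4, the line left out had that direction for 89.4% to 100% with 552A and for 85.4% (Kasumi1) to 94% (MOLM13) with Combo. With ATRA it was 88.1% to 99.1% in 5 lines and 70.6% in Kasumi1, with a median log2 of 0.115 and 10 of 564 genes called there. Mitochondrially encoded genes held 0.307% to 7.588% of the counts of a library.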
